A study of Mus musculus with 6 samples.

How the data were processed

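Total RNA of 6 samples of differentiated mouse inguinal fat cells, 3 control and 3 given 1 uM rosiglitazone for 4 days, was extracted with TRIzol and silica columns, made into biotinylated cRNA and hybridised to Affymetrix mouse 430 2.0 arrays, per the labels. Samples were grouped by their treatment characteristic and title, because the treatment protocol text of the labels gives rosiglitazone for all 6 samples, the controls included. The values used were the authors' deposited table of probe set intensity on a linear scale, 45101 probe sets by 6 arrays. The software for background, summarization and normalization is not given in the sources used here. The values themselves show that the authors had brought the arrays to a common level, since medians ranged from 44.46 to 46.66 and means from 451.9 to 462.7, without making their distributions identical. Between 628 and 736 values per array were exactly 1. How the authors scaled the arrays bears on every direction near 0, so other scalings were tried.

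Probe sets were named through a table of the platform's annotation. Of 45037 probe sets other than the 64 controls, 34945 had 1 gene symbol, 932 had several and 9160 were not listed and stayed unnamed here. A reference table of mouse genes (assembly GRCm38.p6, used for names alone) changed 0 symbols, and no coordinates are given. Intensities under 16 were set to 16, which held for 28.0% to 29.0% of values per array, and log2 was taken. Control probe sets and the 40% of probe sets with the lowest mean were left out, which removed probe sets under an intensity of 26.6. Each gene was represented by its probe set with the highest mean among those with exactly 1 symbol. A gene at or under the floor on all arrays of a group has a lower bound of its fold, written as at least N-fold, and list medians hold such genes at that bound.

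Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend, two-sided, no covariate), with Benjamini-Hochberg adjustment over the 12936 genes tested and a threshold of 0.05. Standard errors and 95% intervals are those of limma. An exact permutation test of 3 against 3 cannot give a two-sided p below 0.1. Gene lists were tested with camera on the same fit (preset correlation 0.01, Benjamini-Hochberg over the lists), with at least 5 measured members. There were 29 lists, from textbook knowledge of fat cells and rosiglitazone and of other cell types that such a culture could hold; 26 were tested. Of the 532 genes in the lists 441 were measured. On simulated data with 200 changed genes among the 12936 the test recovered 58% of changes of 1.2-fold, 88% of 1.5-fold, 98% of 2-fold and 100% of 4-fold, and called 10 unchanged genes (0.0786%). The simulation changed far fewer genes than were called in the data, and the adjusted threshold depends on that share. Its rates of recovery and of false calls therefore do not describe the comparison itself.

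The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the 12 largest rises and the 12 largest falls among called genes whose groups did not overlap, leaving out clone and predicted symbols. It added up to 4 called members per list with the largest absolute change, or 2 members of a list without a call. It also took, whatever their values, Ucp1, Cidea, Ppargc1a, Dio2, Prdm16, Cox8b, Elovl3, Pparg, Fabp4, Adipoq, Tmem26, Tnfrsf9, Tbx1, Lep, Retn, Pdk4 and Pck1. Other members named to identify small counts within a list were chosen after their values were seen. The alternatives were 3 other filters on low values, quantile normalization, median centring, log2(value + 1), a floor of 64, other rules for probe sets, eBayes without a trend or robust, array weights, the replicate number as a block, each array left out in turn, an estimated correlation in camera, limma's fry, an adjusted p under 0.01 and limma's treat against a 1.5-fold change.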

Results

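Gene expression was measured in mouse inguinal fat cells that had been differentiated in culture, on 3 arrays of control cells and 3 arrays of cells given 1 uM rosiglitazone for 4 days. Rosiglitazone is a thiazolidinedione, a drug that activates the nuclear receptor PPARγ, which drives fat cell differentiation. The comparison asked which transcripts differ in these white fat depot cells when the drug is present, and the labels describe the treated cells as undergoing beiging, the gain of heat-producing features by white fat. The median intensity of an array lay between 44.46 and 46.66, and its highest value between 16947 and 17925. Arrays of the same group correlated at 0.973 to 0.978 over all probe sets, and arrays of different groups at 0.964 to 0.967. The number of arrays limits the precision of every value, and nothing in the labels says that the 3 samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

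The 2 largest rises were in Ucp1 and Cidea, genes of heat-producing fat. The intensity of Ucp1, which encodes the protein that uncouples mitochondrial respiration to release heat, was 5.38 ± 1.37 in control cells and 1495 ± 16.9 with rosiglitazone (mean ± SD, n = 3 each), at least 93.4-fold higher because all 3 control arrays lay under the floor of 16. Cidea, which encodes a lipid droplet protein abundant in brown fat, rose from 52.8 ± 6.38 to 4610.5 ± 139.9, a log2 change of 6.46 (SE 0.07, adjusted p = 8.0e-19). The largest fall was in Lep, which encodes the white fat hormone leptin, from 664.6 ± 41.3 to 19.1 ± 7.52, where 1 treated array lay under the floor (log2 change −5.02, SE 0.13, adjusted p = 2.0e-14). Among gene lists, 13 of 14 inflammatory genes and 14 of 15 smooth muscle genes fell, and these list calls held with an estimated correlation (adjusted p = 0.0410 for both). In the same arrays 12 of 13 macrophage markers and 22 of 23 matrix genes fell, and 20 of 20 genes of fatty acid oxidation and 49 of 53 of oxidative phosphorylation rose. The calls of these 4 lists were lost with an estimated correlation (adjusted p = 0.143, 0.0701, 0.0701 and 0.0945 with an estimated correlation). Several general fat cell genes near the top of the array's range did not pass the test, among them Adipoq and Fabp4.

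Of 12936 genes tested, 7661 changed at an adjusted p under 0.05, and 70.8% of these changed by less than 1.5-fold. The 3 arrays of one group lay entirely on one side of the other for 8265 genes, 63.9% of those tested, where chance gives 10%. On the deposited scale 3047 genes were higher and 4614 lower with rosiglitazone, but this split depended on the scaling of the arrays. It was 3935 higher and 3761 lower after quantile normalization. After median centring, which centred each array on the median of the probe sets kept by the filter, it was 4544 higher and 3264 lower. Median centring moved the median log2 change of all genes from −0.05 to 0.07, a shift of 0.12, so the changes given here are relative to the deposited scale and are 0.12 higher on the centred scale for genes well above the floor. Among changes of at least 2-fold, 191 genes were higher and 581 lower as deposited, 219 and 463 after quantile normalization, and 246 and 413 after median centring.

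**Figure D1:**
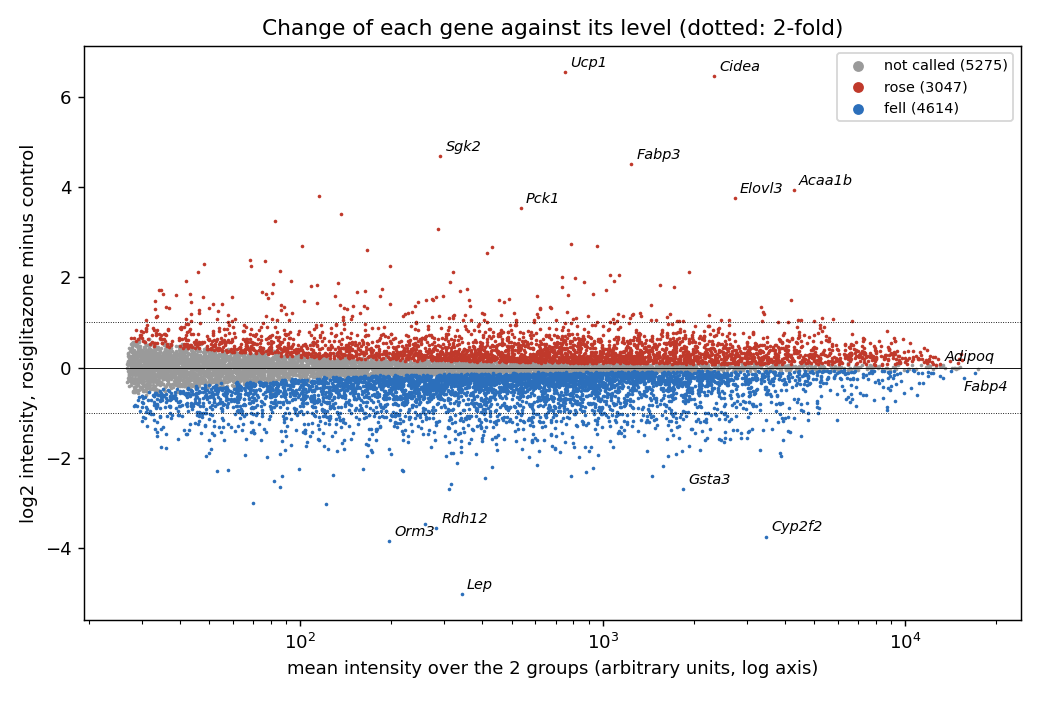
Log2 change of each of the 12936 genes (vertical axis, rosiglitazone minus control) against its mean intensity over both groups (horizontal log axis, arbitrary units). Red points are the 3047 genes that rose, blue points the 4614 that fell and grey points the 5275 that did not pass the test, with 2-fold changes marked by dotted lines.

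The other genes among the 12 largest rises had varied functions. Sgk2, a protein kinase gene, rose by a log2 change of 4.68, and Fabp3, which encodes a fatty acid binding protein of muscle and brown fat, by 4.50 (2.40 with the mean of its probe sets). Acaa1b, a peroxisomal thiolase gene, rose from 528.2 ± 6.20 to 8038 ± 136.9. Elovl3, which encodes an elongase of very long chain fatty acids, rose by 3.76, and Pck1, which encodes the enzyme that supplies glycerol backbones for triglycerides in fat, by 3.53 (1.90 with the mean of its probe sets). Otop1, a proton channel gene, was at least 14.0-fold higher, and Fgf21, which encodes a metabolic hormone, at least 9.46-fold higher, since all 3 control arrays lay under the floor for both. Rbp7, a retinol binding protein gene, rose by 3.40, Nipsnap1 by 3.08 and the glycogen synthase gene Gys2 by 2.73. The adjusted p of these 10 genes lay at or below 9.0e-11.

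The 12 largest falls were likewise varied. After Lep came Orm3, an acute phase glycoprotein gene, which fell by 3.85 on the log2 scale, and the cytochrome P450 gene Cyp2f2, which fell by 3.75 from an intensity of 6442 ± 90.0 to 480.8 ± 35.5. The retinol dehydrogenase gene Rdh12 fell by 3.56 and the retinaldehyde dehydrogenase gene Aldh1a3 fell by 2.64. Adcyap1r1, the receptor gene for the peptide PACAP, fell by 3.46 (−1.60 with the mean of its probe sets), and the early response transcription factor gene Egr3 fell by 3.01 (−1.53 with that mean). Zfp185 fell from 128.1 ± 7.37 to 11.9 ± 5.09, with 2 of its treated arrays under the floor. The glutathione transferase gene Gsta3 fell by 2.70, Cbs, a gene of sulphur amino acid metabolism, fell by 2.68, Cemip, a gene of hyaluronan breakdown, fell by 2.57, and Prss16 fell by 2.51.

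**Figure D2:**
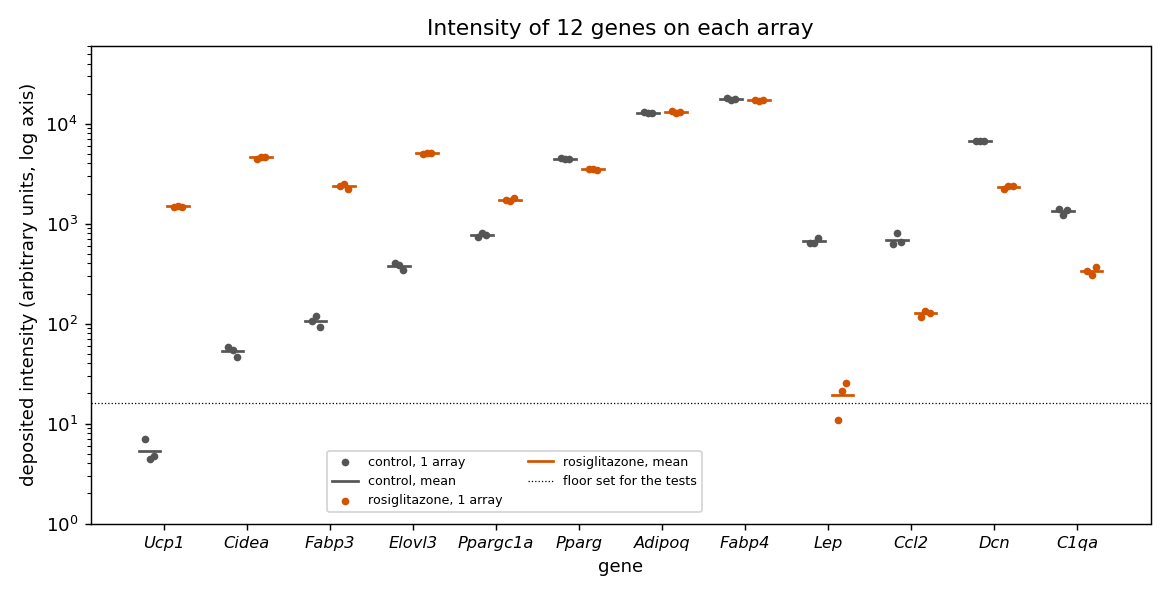
Deposited intensity (vertical log axis, arbitrary units) of 12 genes on each of the 6 arrays, as points with the mean of each group as a line and the floor of 16 as a dotted line. Ucp1, Cidea, Fabp3, Elovl3 and Ppargc1a were higher on all 3 rosiglitazone arrays, Lep, Ccl2, Dcn, C1qa and Pparg were lower, and Adipoq and Fabp4 were bright in both groups (mean 12829 and 17647 in control cells).

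In the thermogenic program list, 17 of 18 measured members rose (17 adjusted over the list alone), with a median log2 change of 1.07. Besides Ucp1, Cidea, Fabp3, Otop1 and Elovl3, the coactivator gene Ppargc1a rose by 1.18 (SE 0.04) and the cytochrome oxidase subunit gene Cox8b by 1.07 (SE 0.05). Prdm16, a transcription factor gene of brown fat, rose by 0.69 (SE 0.09), or by 0.40 with the mean of its probe sets. Dio2, which encodes the enzyme that activates thyroid hormone, rose by 0.27 (SE 0.10, adjusted p = 0.0317), a weak call that was lost without control replicate 1, 2 or 3 or rosiglitazone replicate 2 or 3, where its log2 change was 0.27, 0.27, 0.27, 0.21 and 0.21. Over the 19 alternatives its adjusted p ranged from 0.0023 to 0.14. The remaining member, Esrrg, had a log2 change of 0.26 (adjusted p = 0.239). The list was called by camera (adjusted p = 1.1e-14) and also with an estimated correlation (adjusted p = 0.0410).

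Markers proposed to separate beige from brown or white fat cells did not move together. Among 9 measured members of the list named beige-selective, P2rx5, Slc36a2 and Shox2 rose and Klhl13 and Slc27a1 fell (3 and 2 adjusted over the list alone). That list does not separate markers of beige against white fat from markers of beige against brown fat. P2rx5, an ATP-gated channel gene, rose by 0.52 and Klhl13 fell by 1.09, while the fall of Slc27a1, −0.24 as deposited, was −0.12 and not called after median centring. Tbx1 had a log2 change of 0.14 (SE 0.11, adjusted p = 0.278; 0.27 and called after median centring) and Tnfrsf9 of −0.26 (SE 0.19, adjusted p = 0.254). Tmem26 was too dim to test, its 2 probe sets lying between 4.62 and 23.15 on the 6 arrays. The list was not called (adjusted p = 0.628), and its median of 0.01 and its mean of −0.06 differed in sign. Of 7 classical brown markers, 1 rose and 5 fell, as they did adjusted over the list alone: the adhesion gene Mpzl2 rose by 1.63, while Hspb7 fell by 0.79 and Meox2 fell by 0.71 (list adjusted p = 0.248, median −0.46). In the white-selective list 8 of 13 members fell and 4 rose, also adjusted over the list alone. Lep, Wfdc21 (−1.95), the angiotensinogen gene Agt (−1.15) and Igfbp3 (−0.98) led the falls, Retn, which encodes resistin, fell by 0.87, and Nnat, Slc7a10, Psat1 and Rarres2 rose by 0.25 to 0.69. This list was called (adjusted p = 0.0382, median −0.40), and the call was lost with an estimated correlation (adjusted p = 0.213 with an estimated correlation). It was also lost without a variance trend (adjusted p = 0.121), with a floor of 64 (adjusted p = 0.105) and with the lowest 20% of probe sets left out (adjusted p = 0.0687).

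Among PPARγ target genes, 19 of 26 measured members rose and 2 fell (19 and 2 adjusted over the list alone), with a median log2 change of 0.27. Plin5, which encodes a lipid droplet protein of oxidative tissues, rose by 2.11, the glycerol channel gene Aqp7 by 1.30, the lactate receptor gene Hcar1 by 1.24 (0.22 and not called with a floor of 64), and Pdk4, which encodes a kinase that shuts off pyruvate oxidation, by 1.17. The falls were in Plin4 (−0.17, not called after median centring) and the hormone-sensitive lipase gene Lipe (−0.23). The list was called (adjusted p = 2.3e-08; adjusted p = 0.0410 with an estimated correlation). Pparg itself fell by 0.36 (SE 0.03, adjusted p = 6.7e-09), from 4463 ± 41.7 to 3484 ± 54.2. Adipoq, which encodes adiponectin, had a log2 change of 0.04 (95% CI −0.01 to 0.08, adjusted p = 0.164) at intensities near 13158, and after median centring it rose by 0.16. Fabp4, which encodes the main fatty acid binding protein of fat cells, had a log2 change of −0.04 (95% CI −0.09 to 0.00, adjusted p = 0.104) at an intensity of 17647 ± 326.0 in control cells. Its probe set itself gave the highest value on control arrays 1 and 3 and on rosiglitazone arrays 1 and 3. The change of Fabp4 was −0.05 and called without rosiglitazone replicate 1 and with array weights, and 0.08 and called after median centring. With the mean of its 4 probe sets it was also 0.08 and called. Tested by themselves, 2 of these probe sets were called higher. A comparison covered 22 genes with a brightest probe set over 8000 and a much dimmer one. Only genes whose 2 sets changed in the same direction, by more than a small amount on average, were kept. The brightest set changed less than the dimmer one by a median of 0.31 on the log2 scale. Over 645 genes kept in the same way, with a brightest set between 500 and 2000, the median difference, dimmer minus brightest, was −0.0041. Changes read from such bright sets may therefore be understated, though whether both sets of a gene read the same transcripts was not tested.

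In the adipocyte identity list 13 of 22 members fell and 4 rose (13 and 4 adjusted over the list alone; 12 and 8 after median centring), and the list was not called (adjusted p = 0.0783, median −0.21). It was called without control replicate 2 (median −0.22), after quantile normalization (median −0.17), without a filter on low values and by fry. Its falls were led by the transcription factor genes Cebpd (−1.16), Klf4 (−1.06) and Klf15 (−0.78), and its rises by the adiponectin receptor gene Adipor2 (0.65). Of 20 genes of fatty acid and triglyceride synthesis, 14 fell and 5 rose (14 and 5 adjusted over the list alone). Acss2, which makes acetyl-CoA from acetate, fell by 1.06 and the elongase gene Elovl6 fell by 0.93, while Acacb, whose product makes the malonyl-CoA that restrains fatty acid oxidation, rose by 0.86. The call of this list (adjusted p = 0.0186, median −0.26) was lost with an estimated correlation (adjusted p = 0.361 with an estimated correlation), and also without a variance trend (adjusted p = 0.0567). In cholesterol synthesis 11 of 17 members fell and 4 rose, also adjusted over the list alone. Pmvk fell by 1.04 and Tm7sf2 fell by 0.82, and the list was not called (adjusted p = 0.0789, median −0.40). It was called without control replicate 2 (median −0.36), after median centring (median −0.28), without a filter on low values and by fry.

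All 20 measured genes of mitochondrial fatty acid oxidation rose (20 adjusted over the list alone), with a median log2 change of 0.41 against −0.05 for all genes tested. The thioesterase gene Acot2 rose by 1.14, Hadha, a subunit gene of the trifunctional protein, by 1.06, the thiolase gene Acaa2 by 1.03 and Eci2 by 0.91. Of 18 genes of peroxisomal enzymes 12 rose and 2 fell, the same numbers as adjusted over the list alone. They included Acaa1b, Acot4 (1.48) and Ehhadh (0.97), whose products act in peroxisomal fatty acid breakdown, while Pecr fell by 0.97 and Abcd2 fell by 0.72. In oxidative phosphorylation, a list of respiratory chain and ATP synthase genes, 49 of 53 members rose and 1 fell (50 and 1 adjusted over the list alone). The median was 0.22, and 46 rose and 2 fell after quantile normalization. Ndufa5 rose by 0.68, Cox7c by 0.53, Uqcr10 by 0.46 and Ndufs8 by 0.44. In the tricarboxylic acid cycle 14 of 16 members rose and 2 fell (14 and 2 adjusted over the list alone), with Dlst at 0.63, Sucla2 at 0.59 and the citrate synthase gene Cs at 0.55, and the falls in Suclg2 (−0.22) and Pcx (−0.25). Glycolysis had 10 rises and 3 falls among 15 members (11 and 3 adjusted over the list alone): Pgk1 rose by 0.49 and the glucose transporter gene Slc2a1 fell by 0.93.

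Camera called all 5 of these metabolic lists: oxidative phosphorylation (adjusted p = 1.0e-16), fatty acid oxidation (1.1e-14), the tricarboxylic acid cycle (3.0e-07, median 0.32), peroxisomal enzymes (1.8e-05, median 0.43) and glycolysis (0.0148, median 0.20). The peroxisomal call held with an estimated correlation (adjusted p = 0.0436), and the others did not: fatty acid oxidation and the tricarboxylic acid cycle (adjusted p = 0.0701 with an estimated correlation for both), oxidative phosphorylation (adjusted p = 0.0945 with an estimated correlation) and glycolysis (adjusted p = 0.102 with an estimated correlation). In the list of endoplasmic reticulum and amino acid stress 13 of 18 members rose and 2 fell (13 and 2 adjusted over the list alone). Fgf21 led the rises, followed by the transcription factor gene Ddit3 (0.78) and the pseudokinase gene Trib3 (0.73), while Ddit4, an inhibitor of mTORC1 signalling, fell by 1.24 and Xbp1 fell by 0.10 (0.02 and not called after median centring). The median was 0.41, and the call of this list (adjusted p = 1.0e-05) was lost with an estimated correlation (adjusted p = 0.213 with an estimated correlation).

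**Figure D3:**
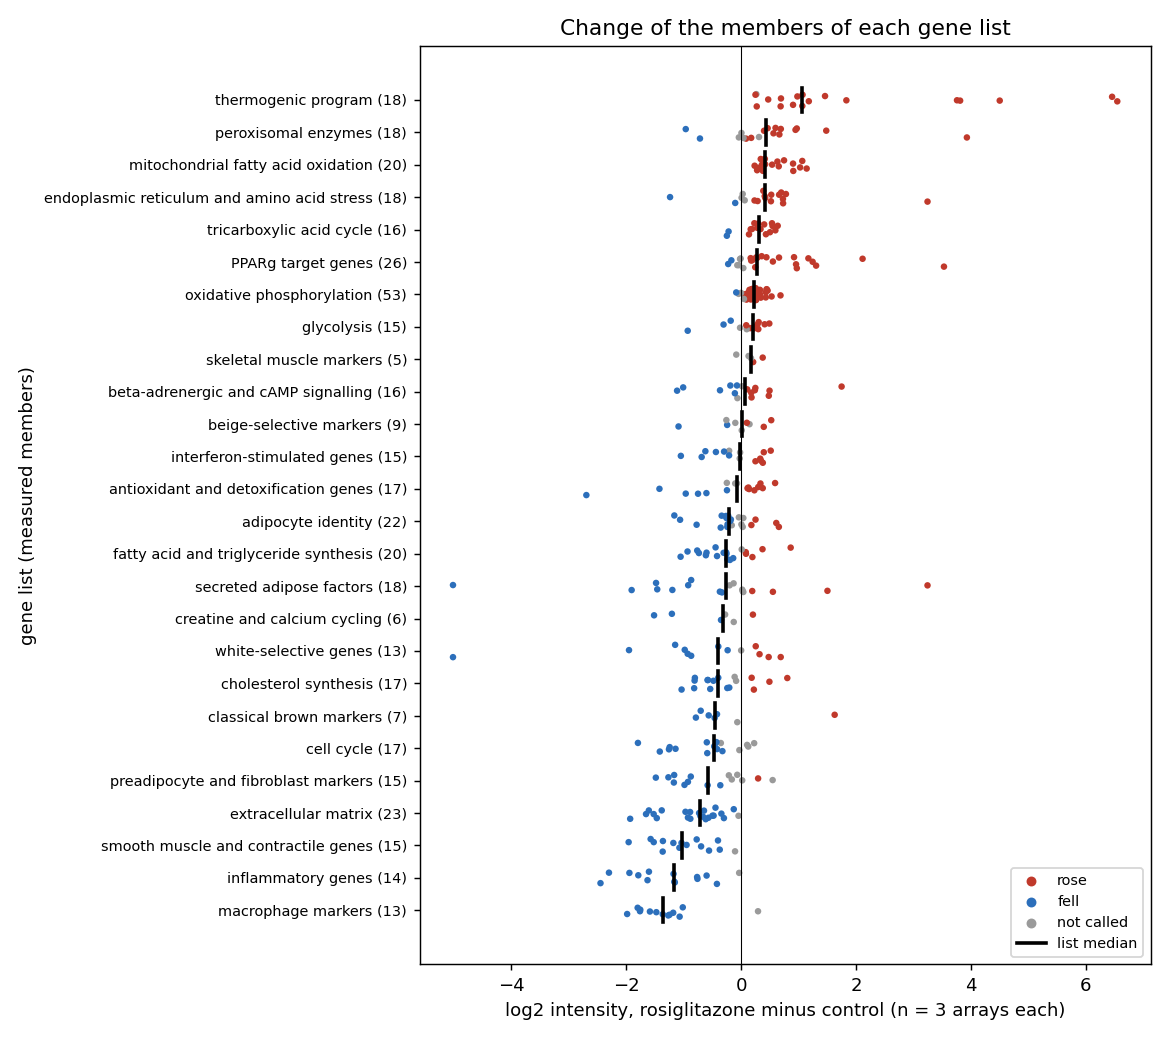
Log2 change (horizontal axis, rosiglitazone minus control) of each measured member of the 26 tested gene lists, with 1 point per gene and a black line at the list's median, lists ordered by median. Red points rose, blue points fell and grey points did not pass the test, and medians ran from −1.37 for macrophage markers to 1.07 for the thermogenic program.

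Macrophage markers fell. Of 13 measured markers 12 fell (12 adjusted over the list alone), with a median log2 change of −1.37. The complement gene C1qa fell from 1334 to 337, the mannose receptor gene Mrc1 fell by 1.80, and C1qb and C1qc each fell by 1.76. The remaining marker, Fcgr1, had a log2 change of 0.29 (adjusted p = 0.305) at a control intensity of 27.0. The call of the list (adjusted p = 1.0e-07) was lost with an estimated correlation (adjusted p = 0.143 with an estimated correlation). Ptprc, the pan-leukocyte gene CD45 in the lymphocyte list, fell by 1.17, while Cd8a and Cd79b did not pass the test, with log2 changes of 0.01 and 0.50. That list had 3 measured members, the endothelial list 4 and the epithelial list 2, too few to test as groups. The endothelial receptor genes Flt1 (−1.57; −0.78 with the mean of its probe sets) and Tek (−1.15) fell, and Sox18 rose by 0.46 from an intensity of 37.2. The probe sets of the other listed endothelial genes, among them Pecam1, Cdh5 and Kdr, did not pass the filter on low values. The falls of Flt1 and Tek therefore cannot be assigned to endothelial cells. The call of Sox18 was lost without control replicate 2 or rosiglitazone replicate 2 or 3 (log2 change 0.32, 0.42 and 0.45), and its adjusted p over 18 alternatives ranged from 0.0081 to 1. The keratin genes Krt8 and Krt19 had log2 changes of 0.15 and −0.00 and did not pass the test. Of 5 skeletal muscle markers 2 rose over all genes, Ckm by 0.37 and Des by 0.21, and 0 rose adjusted over the list alone (list adjusted p = 0.399, median 0.17). Without control replicate 1 or 2 or rosiglitazone replicate 2 or 3 Ckm was not called, at log2 changes of 0.31, 0.33, 0.36 and 0.22. Des was not called without control replicate 1 or 2 or rosiglitazone replicate 1 or 2, at log2 changes of 0.15, 0.21, 0.20 and 0.18. With the replicate number as a block Des was not called either (log2 change 0.21, limma adjusted p = 0.0504).

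Inflammatory genes fell together with the macrophage markers: 13 of 14 members fell (13 adjusted over the list alone), with a median of −1.17. The monocyte chemokine gene Ccl2 fell from 693 to 126, the lipocalin gene Lcn2 fell by 2.30, Il1rn fell by 1.95 (−0.70 with a floor of 64) and the stromelysin gene Mmp3 fell by 1.79. The list was called (adjusted p = 8.8e-07; adjusted p = 0.0410 with an estimated correlation). Interferon-stimulated genes went both ways, with 6 rises and 6 falls among 15 members (6 and 6 adjusted over the list alone), among them falls of Gbp2 (−1.05) and Ifih1 (−0.69). Its median was −0.03 as deposited, 0.05 after quantile normalization and 0.10 after median centring, and the list was not called (adjusted p = 0.813).

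Stromal groups also fell, in the same arrays in which macrophage markers had a median of −1.37. In the extracellular matrix list 22 of 23 members fell (22 adjusted over the list alone), with a median of −0.71, led by the protease inhibitor gene Timp1 (−1.93), Tnc (−1.66), Thbs1 (−1.61) and the proteoglycan gene Dcn (−1.52). The exception, Col6a2, had a log2 change of −0.05, and Postn (−0.13) was not called after median centring. The call of the matrix list (adjusted p = 4.9e-13) was lost with an estimated correlation (adjusted p = 0.0701 with an estimated correlation). Of 15 smooth muscle and contractile genes 14 fell (14 adjusted over the list alone), with a median of −1.04. The smooth muscle myosin gene Myh11 fell by 1.96, the calponin gene Cnn1 fell by 1.58 (0 and not called with a floor of 64), Actg2 fell by 1.52 and Mylk fell by 1.37 (list adjusted p = 2.9e-07; adjusted p = 0.0410 with an estimated correlation). Among 15 preadipocyte and fibroblast markers 9 fell and Gata2 rose by 0.29 (9 and 1 adjusted over the list alone). Cd34 fell by 1.49 (−0.25 with a floor of 64), Thy1 fell by 1.27 and the growth factor receptor gene Pdgfra fell by 1.17, and the call (adjusted p = 0.0035, median −0.58) was lost with an estimated correlation (adjusted p = 0.0811 with an estimated correlation). Of 17 cell cycle genes 12 fell (12 falls and 1 rise adjusted over the list alone). The proliferation marker gene Mki67 fell by 1.80 and Mcm5 fell by 1.42, at control intensities of 78.9 and 100.1 (−0.30 and −0.64 with a floor of 64), and this call (adjusted p = 0.0079, median −0.47) was lost with an estimated correlation (adjusted p = 0.0939 with an estimated correlation).

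The other lists were not called. Among secreted adipose factors 9 of 18 fell and 4 rose (9 and 4 adjusted over the list alone). The growth factor gene Nrg4 rose from 188.5 ± 6.65 to 533.1 ± 6.96 and the matricellular gene Ccn2 fell by 1.91 (list adjusted p = 0.189, median −0.27). In beta-adrenergic and cAMP signalling 8 of 16 rose and 6 fell, also adjusted over the list alone, and 8 rose and 3 fell after median centring. The adenylyl cyclase gene Adcy5 rose by 1.75 (1.12 with the mean of its probe sets), and the regulator gene Rgs2 fell by 1.12 (list adjusted p = 0.286, median 0.06). Of 6 genes of creatine and calcium cycling 3 fell and 1 rose (3 and 1 adjusted over the list alone). Gamt fell by 1.52, the creatine kinase gene Ckb fell by 1.21, Slc6a8 fell by 0.35 and the calcium pump gene Atp2a2 rose by 0.20 (list adjusted p = 0.237, median −0.32). Antioxidant and detoxification genes had 8 rises and 6 falls among 17 members (8 and 6 adjusted over the list alone), the largest of them falls of Gsta3, Gstm1 (−1.42) and Gpx3 (−0.97). The median of this list was −0.07 and its mean −0.29, while the direction of its camera test was up (adjusted p = 0.813), and the median was 0.05 after median centring. In all, 16 of 26 lists were called, 8 higher and 8 lower, and 5 of the 16 held with an estimated correlation. For the preadipocyte, cell cycle and glycolysis lists the estimate was −0.012, −0.012 and −0.014, under the preset 0.01. A higher correlation between genes therefore did not account for the loss of these calls. The other lists that lost their call had estimates of 0.049 to 0.409, but correlation alone cannot be taken as the cause there. Lists with estimates under the preset weakened as well. The estimates were −0.016 for PPARγ target genes, −0.0066 for smooth muscle genes and −0.034 for inflammatory genes. Their camera adjusted p went from 2.3e-08, 2.9e-07 and 8.8e-07 to 0.0410 for each.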

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

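Of the tests here, those on Gapdh, pyruvate carboxylase and the transferrin receptor were chosen after their results were seen. The others were chosen after the actin change but before their own results.

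The control probe sets for beta-actin gave a larger difference between the 3′ and 5′ ends of the transcript with rosiglitazone, 1.29 ± 0.09 against 0.85 ± 0.04 on the log2 scale (SD, n = 3 each), a change of 0.44 (two-sided exact permutation p = 0.1, the smallest this design can give). The same difference for Gapdh changed by −0.0517 (exact permutation p = 0.4), while that of pyruvate carboxylase changed by 0.16 (exact permutation p = 0.4) and that of the transferrin receptor by −0.09 (exact permutation p = 0.6), so degraded or shorter labelled RNA in the treated samples stays open. Compression of bright signals may account for it. The genes compared had a much dimmer second probe set, and both sets changed in the same direction by more than a small amount on average. Among 22 such genes whose brightest set lay over 8000, the dimmer set changed by more in 21, by a median of 0.31. The median was −0.0041 over 645 such genes whose brightest set lay between 500 and 2000 (permutation p = 1e-05, the smallest the resampling could give). Dimmer sets of the latter genes can lie nearer the floor, and the effect of that on their changes was not tested. The actin 3′ probe set was the brighter, at 11260.0 in control and 9285 in treated samples, and the 5′ set lay at 6258 and 3803. A difference in labelling or hybridization also stays open, because the mean 3′ to 5′ difference of 4 bacterial control RNAs changed by 0.0057 with a wide spread between arrays (SD 0.16 and 0.24). All 3 actin sets were lower with rosiglitazone, with log2 changes of −0.28 (3′ end), −0.43 (middle) and −0.72 (5′ end). Whether a change in the form of actin transcripts gave these unequal falls was not tested.

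Probe sets with no single gene name held treatment differences too, at a lower share than named ones. Of 3862 tested, 1427 passed the threshold (36.95%, against 54.1% of named probe sets). Of these 141 changed by at least 2-fold, 44 higher and 97 lower.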

How the results depend on the processing

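Of 132 named genes, 120 kept their direction and side of the threshold in every alternative run on them, and 7 of 26 lists did. The 12 others were Adipoq, Ckm, Cnn1, Des, Dio2, Epsti1, Fabp4, Hcar1, Mx1, Slc27a1, Sox18 and Tbx1. With a floor of 64 the calls of Cnn1, Epsti1, Hcar1, Mx1 and Sox18 were lost at log2 changes of 0, −0.03, 0.22, 0 and 0, since that floor covers their values on at least 3 of the 6 arrays. Ckm, Des and Dio2 also lost their calls there, at unchanged log2 changes; the cause was not tested. Changes that stayed called but shrank by more than 1.5 times with that floor included those of Otop1, Rbp7, Fgf21, Mcm5, Cd34, Mki67, Il1rn, Prss16, Aldh1a3, Zfp185, Egr3 and Orm3, and with the mean of a gene's probe sets those of Fabp3, Pck1, Adcy5, Prdm16, Sucla2, Slc6a8, Flt1, Egr3 and Adcyap1r1. Without probe sets that can bind several transcripts Mcm5 was −0.50, Aqp7 1.96 and Meox2 −1.38, and after median centring Pparg was −0.23 and Slc6a8 −0.23. Testing each probe set by itself called 13962 probe sets (5703 higher, 8259 lower, 1406 by at least 2-fold), which follows from 27022 features being tested, and testing against a 1.5-fold change with treat called 1202 genes (321 higher, 881 lower), which leaves out small changes by construction. With an estimated correlation camera called 5 lists. Other settings called 14 to 24 lists, the highest with fry, which does not compare a list with other genes. Fabp4, at −0.04 and not called in the comparison as reported, was called at 0.08 (0.081) after median centring, which raised changes well above the floor by 0.12. With the mean of its probe sets Fabp4 was called at 0.08 (0.075), and 2 of its 4 probe sets were called higher when tested by themselves. The antioxidant list was called downward by fry with a median of −0.0741, and the cause of that was not tested. After median centring 6311 of the 7661 genes were called again and 0 in the opposite direction; with the mean of a gene's probe sets 6659 were, and 28 were called in the opposite direction. Leaving out 1 array at a time called 6946 to 7420 genes (2716 to 2945 higher, 4230 to 4488 lower, 758 to 793 by at least 2-fold) and 16 to 18 lists; the calls of Dio2, Ckm, Des, Mx1 and Sox18 were each lost in 3 to 5 of these 6 fits, Des at log2 changes of 0.15 to 0.21 and Mx1 at 0.33 to 0.54. A fit with the replicate number as a replicate block called 7665 genes (3045 higher, 4620 lower); deviations of samples with the same number correlated at −0.03, −0.03 and 0.06.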

Other observations

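The gene families in the first paragraphs, the genes named from them, the comparison of macrophage with stromal markers and the count of list calls over other splits were chosen after the main results were seen.

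Genes of mitochondrial protein synthesis and import rose along with those of oxidative phosphorylation. Of 76 measured genes of mitochondrial ribosomal proteins 71 rose and 1 fell, with a median log2 change of 0.39 (camera adjusted p = 2.4e-23 over 26 families, adjusted p = 0.0256 with an estimated correlation). Mrpl46 rose by 0.96 and Mrpl34 by 0.76. Of 22 genes of the mitochondrial import machinery 19 rose and 1 fell, with a median of 0.40 (adjusted p = 1.7e-09, adjusted p = 0.0353 with an estimated correlation), led by Timm9 at 1.15 and Timm8a1 at 0.92. Genes of cytosolic ribosomal proteins gave no such pattern: 3 of 44 rose and 12 fell as deposited, 5 rose and 23 fell after quantile normalization, and 23 rose and 1 fell after median centring. Of 37 proteasome subunit genes 23 rose and 2 fell, the immunoproteasome subunit genes Psmb9 (−0.87) and Psmb10 (−0.36) being the falls (adjusted p = 2.9e-04, adjusted p = 0.127 with an estimated correlation).

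Immediate early genes, which respond within minutes to growth factors and stress, fell in 22 of 28 cases, with a median of −0.70 (adjusted p = 1.5e-05, adjusted p = 0.127 with an estimated correlation). Egr1 fell by 1.86 and Fos fell by 1.54. Of 18 clock genes 15 fell and 2 rose as deposited, 12 and 2 after quantile normalization and 11 and 2 after median centring (adjusted p = 0.0043, adjusted p = 0.127 with an estimated correlation). Bhlhe40 fell by 1.21 and Rora fell by 0.84. In the insulin-like growth factor system 8 of 10 genes fell, among them Igf1 (−1.48), Igfbp4 (−1.18) and the receptor gene Igf1r (−0.90), with adjusted p = 4.4e-04 (adjusted p = 0.262 with an estimated correlation). Metalloproteinase genes fell in 19 of 36 cases and rose in 1, with Adamts5 at −1.57 and Mmp12, a gene expressed by macrophages, at −1.52 (adjusted p = 0.0010, adjusted p = 0.127 with an estimated correlation). In the same arrays the medians of macrophage markers, smooth muscle genes and matrix genes were −1.37, −1.04 and −0.71, and whether the growth factor and metalloproteinase genes fell apart from those groups was not tested.

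The fall of macrophage markers may come from fewer macrophages, or less RNA from them, in the treated cultures. A second list of 38 myeloid genes, none of them in the lists fixed beforehand, had 31 measured members, of which 25 fell (80.6%) and 1 rose, with a median log2 change of −1.07, and 0 of 10000 random lists matched on level had a median as low. Random lists draw unrelated genes, while the macrophage markers had an estimated correlation of 0.41, so this count cannot tell causes apart. A drop of all non-fat cells together remains open: preadipocyte and fibroblast markers had a median of −0.58, closer to 0 than macrophage markers (permutation p = 0.0117 over genes, which are not independent), but smooth muscle genes had one of −1.04. Lower expression of these genes within macrophages, or a direct effect of the drug on genes that fat cells share with them, was not tested.

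The excess of lower over higher calls among all called genes may come from the authors' scaling of the arrays. With each array centred on the median of the probe sets kept by the filter 41.8% of called genes were lower, against 60.2% as deposited. Among changes of at least 2-fold the excess stayed under each scaling tried. There 581 genes were lower and 191 higher as deposited, 463 and 219 after quantile normalization, and 413 and 246 after median centring. Since the scaling method is not given in the sources used here, whether the deposited or the centred scale is nearer to the RNA content of the cells cannot be told apart. The real grouping called 7661 genes and the highest other of the 10 splits of the 6 arrays into 3 and 3 called 0, so only 1 split, the real grouping, gave as many genes, and 10 splits are too few for a share under 0.05. For gene lists the real grouping called 16 and the highest other split called 13, so again 1 split gave as many and the splits are too few. Each of the other splits sets 2 arrays of a treatment with 1 of the other and so keeps a share of the treatment difference, and their list counts do not show how many lists are called without one.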
